A study of Mus musculus with 12 samples.

How the data were processed

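RNA was sequenced from B16.F10 mouse melanoma cells in 12 libraries, 3 in each of 4 groups. Cells received a small interfering RNA against luciferase (siLuc, the control) or against Prmt7 (siPRMT7) for 72 h, and a group of each kind was exposed to interferon gamma (IFN-γ) for the last 24 h, per the labels' protocols. Libraries were made with a strand-marking poly(A) kit and read as single reads, per the labels' protocols. The unit of the IFN-γ amount differs between the labels, so no dose is printed. The labels name the libraries of a group as replicates and do not say that they came from separate cultures. The p-values therefore measure the spread between these libraries only, which may be technical.

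The deposited table holds 55536 genes with a value per library and, beside them, the authors' own comparisons. Per the file headers, the per-library values are regularized log (rlog) values on a log2 scale, made by the authors from read counts that are not used here. Such values are scaled for library size, and values of genes with few reads are drawn toward the mean over all libraries, so changes of weakly expressed genes are understated. Per the submitters' processing notes, the tools were Trimmomatic 0.39, STAR 2.7.1a, HOMER 4.11.1 and DESeq2 1.26.0, and the genome build was mm10 (GRCm38). Whether the counting used the strand of the reads is not given in the sources used here, so reads of overlapping genes on opposite strands may be mixed. The authors' log2 fold changes and adjusted p-values, per the file headers, stand in the same table for 4 comparisons; the method of adjustment is not given in the sources used here. In the IFN-γ comparison of siLuc cells, 26188 genes have no fold change in the authors' deposited table. All per-library columns were mapped to a sample by name. Coordinates are those of the table, on mm10. Of the 55536 genes, 55450 have an identifier of the GENCODE mouse annotation used here for overlaps, and 43447 have identical coordinates in it.

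Library totals stand in the column names and ran from 18.971 to 30.978 M reads. The values ran from -2.22 to 17.9, and 21981 genes were at 0 in every library. Genes with a mean rlog value of at least 4 over the 12 libraries were tested. Where a symbol stood on more than 1 line (115 symbols), the line with the highest mean was kept, leaving 14407 genes. The median SD within groups was 0.14 on the log2 scale for genes with a mean rlog value of 4 to 6, 0.073 for 8 to 10 and 0.047 for 12 to 14. At 4 to 6 it was 0.53 times the SD that counting alone would give, taking 2 to the power of the rlog value as reads. The spread of weakly expressed genes may thus be understated too, and their p-values too small.

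Differences were tested with limma 3.58.1 in R 4.3.3 (group means of all 12 libraries, moderated variances with a mean-variance trend, 2-sided tests) and adjusted by the method of Benjamini and Hochberg over the genes tested. A gene was called at an adjusted p under 0.05. The fit had 8 residual and 12.4 prior degrees of freedom, and the median residual SD was 0.0751. The comparisons were siPRMT7 against siLuc without and with IFN-γ, IFN-γ against none in siLuc and in siPRMT7 cells, and the difference of the IFN-γ responses (the interaction). A test against a null of a 2-fold change (limma's treat) was added later. The replicate number was not in the model.

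The comparisons, tests, 23 gene lists, alternatives and the rule for named genes were set before the data were examined. The lists were arginine methyltransferases with Wdr77, MHC class I and class II antigen presentation, IFN-γ receptor and JAK-STAT signalling, and interferon-inducible GTPases. They were also type I interferon-stimulated antiviral genes, cytosolic nucleic acid sensing, chemokines and cytokines, and immune checkpoint and immune evasion genes. Short names below stand for whole lists, such as chemokines for chemokines and cytokines. The others were pigmentation, dedifferentiation and mesenchymal genes, DNA methylation and retroelement silencing, Sm proteins and snRNP assembly, cell cycle, p53 pathway, unfolded protein and integrated stress response, heat shock, cholesterol biosynthesis, glycolysis and hypoxia, mitochondrially encoded genes, ribosomal proteins, and markers of leukocytes and of fibroblasts, endothelium and keratinocytes. Lists with at least 3 measured members were tested (22 lists). List tests used camera in limma with a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and calls are given beside camera with an estimated correlation. Counts of called members are given over all genes and adjusted over the list alone.

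Named in each comparison were Prmt7, the 8 genes with the largest rise and the 8 with the largest fall among called genes with a mean rlog value of at least 6 whose groups did not overlap, and up to 3 called members of each list with the smallest p. Predicted genes were left out of this choice. In the interaction the 8 genes with the smallest p in each direction were taken. Irf1, Nlrc5, B2m, H2-K1, Cd274, Cxcl10, Ddx58, Ifih1, Dnmt1, Dnmt3a and Dnmt3b were always examined. Some genes that these rules name are not reported here. After the data were seen, a test of the methyltransferase list without Prmt7 was added, as were 3 lists (NF-κB targets, small nucleolar RNA host genes and neuronal genes that REST represses). Technical explanations were tested with 10000 random lists matched on mean level, with other scalings, and with counts of called genes under other splits of the libraries (all 10 for a pair of groups, 100 drawn assignments for the interaction).

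The procedure was tested on simulated data of 14407 genes with 200 changed genes, 50 of each size, with each gene's real mean and residual SD, normal noise and no other difference between groups. For siPRMT7 against siLuc without IFN-γ it recovered 14% of genes changed by 0.15 on the log2 scale, 48% at 0.3, 92% at 0.6 and 100% at 1, and 3.79% of its calls were false. With IFN-γ the shares were 16%, 56%, 90% and 100%, with 5.07% false calls. For IFN-γ in siLuc cells they were 14%, 60%, 92% and 98% (5.71% false), and in siPRMT7 cells 12%, 68%, 94% and 100% (3.52% false). For the interaction they were 0%, 38%, 78% and 96%, with 7.02% false calls. Only 200 of 14407 simulated genes changed, whereas 30.6% (interaction) to 75.2% (siPRMT7 without IFN-γ) of genes were called in the data. The adjustment is less strict where more genes change, so these shares do not describe recovery in the real comparisons.

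The alternatives were no filter on low values (33486 genes), a mean rlog value of at least 6 (11974 genes), quantile normalization, median centring, variances without the trend, robust variances, library weights, a fit of the compared libraries only, the replicate number as a block, every line as its own feature (14424), a minimum log2 difference of 1, leaving out each library, and other list tests (camera with an estimated correlation, fry). Exons shared between genes were counted on the annotation. Of 203 genes chosen by these rules, 67 share exon bases with another tested gene, 52 of them on the opposite strand. Members of the Gbp, Tgtp, H2, Ifit3, Oas1 and Hspa1 families resemble each other, so their single values are uncertain where the counting could split reads. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and statmod 1.5.0.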

Results

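The data describe the transcriptome of B16.F10 cells, a mouse melanoma line of C57BL/6 origin, after knockdown of Prmt7, with and without interferon gamma (IFN-γ). Prmt7 encodes an arginine methyltransferase that forms monomethylarginine. IFN-γ is a T cell cytokine that acts through a receptor bound by the kinases JAK1 and JAK2. Poly(A) RNA was sequenced in 3 libraries for each of 4 groups: control cells (siLuc, a small interfering RNA against luciferase, which mouse cells lack) without and with IFN-γ, and siPRMT7 cells without and with IFN-γ. Library totals, in M reads, were 24.156 to 25.521 M in siLuc cells without IFN-γ and 22.04 to 28.187 M with it. They were 26.034 to 30.978 M in siPRMT7 cells without IFN-γ and 18.971 to 25.943 M with it. All values are the authors' rlog values on a log2 scale, and differences are log2 differences of group means with a standard error (SE). The SE comes from the moderated variance shared by all 4 groups, so it may understate the spread of a single group. Fold values computed from them are those of the rlog scale.

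Prmt7 (ENSMUSG00000060098.11, mm10 chromosome 8, 106210936 to 106252794, plus strand) had rlog values of 10.16, 10.34 and 10.24 in the siLuc libraries without IFN-γ and 10.26, 10.24 and 10.26 in those with it. The siPRMT7 libraries had 6.16, 6.32 and 6.41 without IFN-γ and 6.36, 6.30 and 6.08 with it. The group means were 10.25 ± 0.09, 10.25 ± 0.02, 6.30 ± 0.12 and 6.25 ± 0.15 (SD, n = 3). Prmt7 was 15.4-fold lower in siPRMT7 than in siLuc cells without IFN-γ (log2 difference -3.95, SE 0.08, adjusted p = 6.39e-20). With IFN-γ it was 16.1-fold lower (-4.005, SE 0.08, adjusted p = 2.73e-20). The authors' deposited table gives -4.34 and -4.49 for the same comparisons. IFN-γ itself left no difference in Prmt7 past the threshold in siLuc cells (0.01, adjusted p = 0.938) or siPRMT7 cells (-0.05, adjusted p = 0.639).

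The 4 groups stood apart as a whole. The first principal component held 62.2% of the variance and ordered the groups siLuc, siPRMT7, siLuc with IFN-γ and siPRMT7 with IFN-γ, and the second held 31.4%. Transcripts of the mitochondrial genome made up 1.83 ± 0.35% of the summed linear values in siLuc cells, 1.11 ± 0.08% in siLuc cells with IFN-γ, 2.68 ± 0.15% in siPRMT7 cells and 1.57 ± 0.03% in siPRMT7 cells with IFN-γ (SD, n = 3). Only 7 of the 13 genes in the mitochondrially encoded list passed the filter on the mean, and mt-Co2, mt-Co3 and mt-Atp6 did not. These shares may therefore miss part of the mitochondrial transcripts, and the cause was not tested. Of the leukocyte markers, Cd68 and Csf1r were the only members measured.

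**Figure D1:**
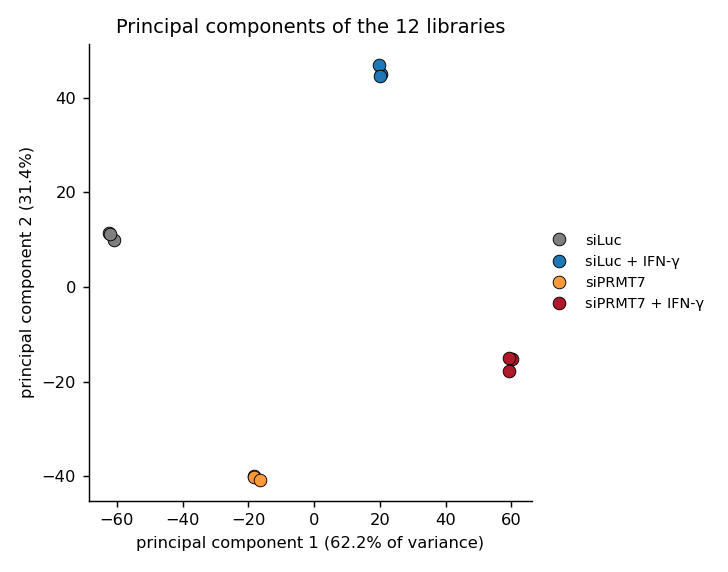
Principal components 1 (x axis, 62.2% of variance) and 2 (y axis, 31.4%) of the rlog values, 1 point per library, coloured by group (n = 3 each). The libraries of each group lie together and the 4 groups lie apart.

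Without IFN-γ, 31 of 32 antiviral genes were higher in siPRMT7 than in siLuc cells and 30 of 32 cell cycle genes were lower, though neither list was called with an estimated correlation (adjusted p = 0.1005 and adjusted p = 0.104). Mx2, an antiviral GTPase, rose 11.9-fold (log2 3.57, SE 0.05, n = 3 per group), from 6.71 ± 0.07 to 10.28 ± 0.11. Gbp3, a guanylate-binding protein gene, rose by 2.76 (SE 0.04), from 6.84 ± 0.02 to 9.60 ± 0.06. Top2a, the topoisomerase of dividing cells, fell by 2.003 (SE 0.05), from 13.43 ± 0.10 to 11.42 ± 0.05. The comparison asks what loss of Prmt7 RNA changes in cells not given the cytokine.

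Of the 32 antiviral genes measured, 31 rose, 0 fell and 1 was not called (32 rose adjusted over the list alone). Their median difference was 1.85, and 24 rose at least 2-fold. Xaf1 rose by 2.87 and Parp14, a mono-ADP-ribosyltransferase, by 2.23. The list was called by camera (adjusted p = 6.52e-18), and the call was lost with an estimated correlation (adjusted p = 0.1005). Among the 17 interferon-inducible GTPases, which act against intracellular pathogens, 10 rose and 0 fell (median 0.95, camera adjusted p = 7.81e-05; adjusted p = 0.227 with an estimated correlation). Irgm2 rose by 3.09 and Irgm1 by 2.18. In the list for MHC class I presentation 16 of 22 members rose and 4 fell (median 0.72, camera adjusted p = 0.000241; adjusted p = 0.104 with an estimated correlation). H2-K1 rose by 2.09, Tapbp, which loads peptides, by 1.86, H2-D1 by 1.68 and Nlrc5, the transactivator of class I genes, by 1.53. B2m rose by 0.67. Of 17 genes for sensing of cytosolic nucleic acids, 12 rose and 1 fell (median 0.57, camera adjusted p = 0.000924; adjusted p = 0.104 with an estimated correlation). Ddx58, which encodes RIG-I, rose by 2.07, Ifih1, which encodes MDA5, by 1.74 and Eif2ak2 by 1.44. In JAK-STAT signalling 13 of 20 members rose and 4 fell (median 0.22, camera adjusted p = 0.0283; adjusted p = 0.286 with an estimated correlation). Stat2 rose by 1.499, Irf9 by 1.23 and Irf1 by 0.23.

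Cell cycle genes moved the other way. Of 32 measured, 30 fell, 27 of them at least 2-fold, and 2 rose (median -1.35, camera adjusted p = 2.92e-14; adjusted p = 0.104 with an estimated correlation). Birc5 fell by 1.86 and Ccna2, cyclin A2, fell by 1.58. In the p53 pathway list 15 of 20 members rose and 3 fell (median 0.66, camera adjusted p = 0.000241; adjusted p = 0.104 with an estimated correlation). Cdkn1a, the inhibitor of cyclin-dependent kinases, rose by 1.04, Sesn2 by 1.14 and Trp53inp1 by 1.08. Of 20 Sm and snRNP assembly genes, whose products build the spliceosome and include arginine-methylated proteins, 16 fell and 0 rose (median -0.52, camera adjusted p = 2.87e-05; adjusted p = 0.1005 with an estimated correlation). Snrpb fell by 1.32. Of 21 glycolysis and hypoxia genes 18 fell (median -0.75, camera adjusted p = 0.000348), with Gapdh at -1.04 and Pfkp at -1.01, and of 20 cholesterol synthesis genes 15 fell and 3 rose (median -0.43, camera adjusted p = 0.00415). Both lists had an adjusted p = 0.494 with an estimated correlation. Of 30 ribosomal protein genes 22 fell and 2 rose (median -0.16, camera adjusted p = 0.00331; adjusted p = 0.494 with an estimated correlation), and this median was 0.03 under quantile normalization. Of 13 dedifferentiation and mesenchymal genes 9 rose and 1, the receptor kinase gene Axl, fell by 0.75 (median 0.61, camera adjusted p = 0.00505; adjusted p = 0.1005 with an estimated correlation). Jun rose by 1.36.

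Of 9 measured genes of the arginine methyltransferase list, Prmt7 and Wdr77 included, 6 fell and 1 rose, with Prmt1 at -0.91 and Prmt5 at -0.55. The list had a median of -0.50 (camera adjusted p = 0.0341; adjusted p = 0.228 with an estimated correlation). Part of this call was fixed by the knockdown: without Prmt7, an alternative chosen after seeing the data, the list was not called (median -0.33, camera adjusted p = 0.0954). Dnmt1, the maintenance DNA methyltransferase, fell by 1.07, Dnmt3a fell by 0.85 and Dnmt3b fell by 0.53. Their list of 30 DNA methylation and silencing genes, with 7 higher and 18 lower, was not called (median -0.19, camera adjusted p = 0.0609). Uhrf1 fell by 1.19 and Ezh2 fell by 0.98. Besides Mx2, the largest rises were Efcab1 at 3.76, Trim12c at 3.68, the small nucleolar RNA host Snhg12 at 3.43, Fyb at 3.35, Abcc2 at 3.17, Stmn4 at 3.12 and the calcium channel gene Cacna1a at 3.10. After Prmt7, the largest falls were Gcat at -2.34, Gamt at -2.33, Pmp22 at -2.31, Sgk2 at -2.30, Pcolce at -2.23, Cip2a at -2.19 and Rab3il1 at -2.16.

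The other lists were not called by camera. For MHC class II, 3 of 8 rose and 1 fell (median 0.07, and -0.12 under quantile normalization). Of 20 chemokines and cytokines 9 rose and 4 fell, including Ccl2 at 1.88, Cxcl1 at 1.34, Ccl5 at 1.256 and Cxcl10 at -0.18 (a call lost under quantile normalization, -0.031, adjusted p = 0.510). Of 14 checkpoint and immune evasion genes 6 rose and 2 fell. Lgals3 rose by 2.84 and Cd274, which encodes PD-L1, by 0.50. Pigmentation genes split into 7 higher and 10 lower of 18, with Mc1r at 0.93 and Mlana at -0.69. Of 25 unfolded protein and integrated stress response genes 8 rose and 14 fell, with Atf3 at 2.08 and the chaperone-related Manf at -1.57 and Pdia6 at -1.35. Of 13 heat shock genes 3 rose and 9 fell (median -0.23, and 0.03 under quantile normalization), with Hspe1 at -1.258. All 7 mitochondrially encoded genes measured rose (median 0.30, camera adjusted p = 0.0663), beside the mitochondrial share given above. Cd68 rose by 1.20, and of 3 markers of fibroblasts and other cells Col1a2 rose by 0.63 while Col1a1 and Pdgfra were at -0.50 and -0.42. Adjusted over the list alone, counts in this comparison were the same except for the antiviral genes.

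In all, 10835 of 14407 genes (75.2%) were called without IFN-γ, 5236 higher and 5599 lower in siPRMT7 cells (5672 and 5168 under median centring). Most differences were small: the median size of called differences was 0.45, and 670 genes rose and 509 fell at least 2-fold. Against a null of a 2-fold change, 365 were higher and 263 lower. The authors' deposited table calls 9561 of the genes tested, 9543 of them also called here in the same direction. As in the other comparisons of a pair of groups below, further genes called here were not called there. The 3 libraries of each group did not overlap for 76.3% of genes, where chance gives 10%. The untreated siPRMT7 library of replicate 3 was the highest of its group at 18 of the 20 genes most induced by IFN-γ, with a median excess over the lowest library of 0.179% of the treated level. Without it the antiviral median was 1.81 and 10333 genes were called. Untreated siLuc libraries of replicates 1 and 3 had excesses too, with medians of 0.0343% and 0.0255% and single genes up to 1.27% and 0.856%.

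**Figure D2:**
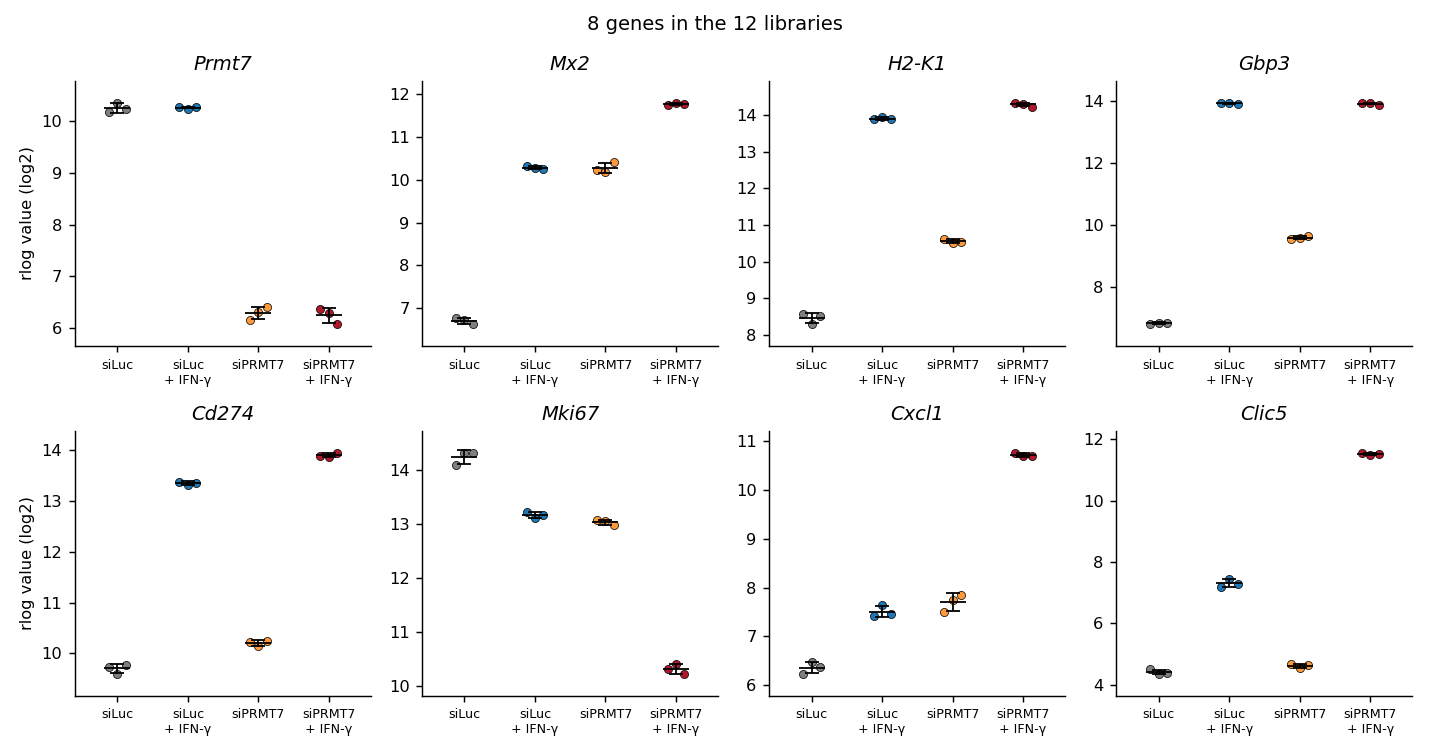
rlog values (y axis, log2) of 8 genes in the 4 groups (x axis), 1 point per library, with a line for the mean and bars for the SD (n = 3). Mx2 was at 6.71 in siLuc and 10.28 in siPRMT7 cells without IFN-γ and at 10.29 and 11.78 with it, while Mki67 was lowest, at 10.31, in siPRMT7 cells with IFN-γ. The y axes do not start at 0.

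With IFN-γ present in both groups, 16 of 32 antiviral genes were higher and 12 lower in siPRMT7 cells, while 31 of 32 cell cycle genes were lower (adjusted p = 0.178 for the cell cycle list with an estimated correlation). Clic5, a chloride intracellular channel gene, was 18.5-fold higher in siPRMT7 cells (log2 4.21, SE 0.09, n = 3 per group), at 11.52 ± 0.03 against 7.31 ± 0.13. Cxcl1, a neutrophil chemokine, was higher by 3.20 (SE 0.09) and Ubd, a ubiquitin-like modifier, by 3.28 (SE 0.08). Top2a fell by 3.07 (SE 0.05), from 12.94 ± 0.02 to 9.88 ± 0.08. The comparison asks what Prmt7 knockdown changes in cells that receive the cytokine.

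Of 32 cell cycle genes 31 were lower, 30 of them at least 2-fold, and 1 was higher (median -2.32, camera adjusted p = 4.59e-20; adjusted p = 0.178 with an estimated correlation). Birc5 fell by 3.24 and Mcm5, of the replicative helicase, fell by 2.74. The mitotic genes Kif11, Espl1, Kif14, Cenpe and Kntc1 were at -3.40, -3.32, -3.26, -3.24 and -3.16, among the 8 largest falls. In the p53 list 15 of 20 were higher and 4 lower (median 0.68, camera adjusted p = 0.000271; adjusted p = 0.178 with an estimated correlation), including Cdkn1a at 1.34, Trp53inp1 at 1.11 and Mdm2 at 0.75. Of 20 Sm and snRNP assembly genes 17 were lower and 0 higher (median -0.39, camera adjusted p = 0.000402; adjusted p = 0.178 with an estimated correlation), with Snrpb at -1.21 and Snrpc at -1.03. All but 1 of 20 cholesterol synthesis genes were lower, 8 at least 2-fold (median -0.86, camera adjusted p = 2.55e-06; adjusted p = 0.510 with an estimated correlation). Lss fell by 1.31 and Hmgcs1, at an early step of the pathway, fell by 1.23. Of 21 glycolysis and hypoxia genes 15 were lower (median -0.40, camera adjusted p = 0.0158; adjusted p = 0.735 with an estimated correlation). Of 20 chemokines and cytokines 10 were higher, 8 at least 2-fold, and 3 lower (median 0.21, camera adjusted p = 0.0324; adjusted p = 0.510 with an estimated correlation). Ccl2 was higher by 2.48 and Ccl5 by 2.10.

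The interferon lists were not called here. Of the antiviral genes 16 were higher, 12 lower and 4 not called (median 0.16, camera adjusted p = 0.249), with Mx2 at 1.49, Samd9l at 0.68 and Oas1a at -0.70. Of the GTPases 3 were higher, 6 lower and 8 not called (median -0.07, and 0.07 under quantile normalization), with Gvin1 at 1.27, Gbp2 at -0.87 and Gbp5 at -0.77. Of the class I genes 6 were higher and 11 lower (median -0.13), with H2-Q4 at 2.05, Calr at -1.58 and Pdia3 at -0.86. H2-K1 was at 0.38 (adjusted p = 1.14e-06), B2m at -0.04 (adjusted p = 0.447) and Nlrc5 at 0.26. B2m turned to 0.29 under quantile normalization and was called there (adjusted p = 0.000197). The class II genes H2-Aa, Cd74 and H2-Ab1 were higher by 1.93, 1.94 and 1.25, and 5 of 8 members were higher and 3 lower (median 0.60, camera adjusted p = 0.157). Ddx58 was higher by 0.35, while Ifih1 was at 0.10 (adjusted p = 0.0895, and 0.00238 under quantile normalization) and Cxcl10 at -0.00 (adjusted p = 0.994). The Cxcl10 value turned to 0.27 under quantile normalization and was called there (adjusted p = 8.53e-06). Irf1 fell by 0.37. Of the signalling genes 7 were higher and 9 lower, with Ifngr2, a chain of the IFN-γ receptor, at 1.06, Stat2 at 0.87 and Ptpn6 at -1.45. The nucleic acid sensing list had 5 higher and 7 lower of 17, with Samhd1 at -1.51, Cgas at -0.74 and Tmem173, which encodes STING, at -0.57. The medians of the signalling and sensing lists (-0.05 and -0.01) turned to 0.04 and 0.07 under another scaling.

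Among other lists, the 14 checkpoint and immune evasion genes had 6 higher and 4 lower. Lgals3 at 2.14 and Cd274 at 0.55 were higher and Cd276 at -0.60 was lower. Uhrf1 fell by 2.51, Dnmt1 fell by 1.63, Hells fell by 1.53, Dnmt3a fell by 0.66 and Dnmt3b fell by 0.32, within 7 higher and 18 lower of 30 silencing genes (camera adjusted p = 0.0865). Prmt1 fell by 0.89 and Prmt3 fell by 0.67, within 2 higher and 5 lower members of the methyltransferase list. Oca2 was at 1.51, Mlana at -0.73 and Slc45a2 at -0.68, within 5 higher and 10 lower of 18 pigmentation genes. Ccn2 was at 1.77 and Sox9 at 1.66, within 9 higher and 4 lower of 13 dedifferentiation genes. Pdia6, Manf and Pdia4 were at -1.61, -1.56 and -1.38, within 10 higher and 14 lower of 25 stress response genes. The heat shock list had 5 higher and 5 lower, with Hspe1 at -1.21, Hspd1 at -0.83 and Hspb1 at 1.52, and its median of -0.02 and mean of 0.04 differed in sign; under another scaling the median was 0.07 or 0.09. Of the mitochondrially encoded genes 6 of 7 were higher, and of the ribosomal protein genes 3 were higher and 17 lower. Cd68 was higher by 1.85 and Csf1r by 0.35. Csf1r (mean rlog value 8.56) shares 15.1% of its exon bases with the higher Hmgxb3 (11.08) on the opposite strand, so its value is uncertain. Col1a2 was at 1.62, Col1a1 at -0.59 and Pdgfra at 0.30 (adjusted p = 0.0251), a call lost under 5 alternatives, among them quantile normalization (adjusted p = 0.191). Adjusted over the list alone, 17 antiviral genes, 8 signalling genes and 7 mitochondrially encoded genes were higher, and other counts were the same.

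Besides the genes given above, the largest rises were Efcab1 at 3.46, Snhg12 at 3.45, Nlrp10 at 3.41, Stmn4 at 3.41 and Cacna1a at 3.20, and Pmp22 was at -3.21. In all, 10757 genes were called, 5179 higher and 5578 lower, and the majority turned to 5623 higher and 5272 lower under quantile normalization and to 6217 and 4745 under median centring. At least 2-fold differences were 562 rises and 711 falls, and against a null of a 2-fold change 316 and 455. The authors' deposited table calls 9535 of the genes tested, 9495 of them also called here in the same direction. The 3 libraries of each group did not overlap for 77.2% of genes, where chance gives 10%.

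The effect of siPRMT7 without IFN-γ and its effect with IFN-γ come from different libraries. Across the 14407 genes they correlated with a Pearson r of 0.833 (jackknife SE over libraries 0.00464) and a Spearman rho of 0.854. Genes are not independent replicates, so no p is given. Of 9138 genes called in both, 8722 (95.4%) had the same sign and 416 the opposite sign. All 770 genes that changed at least 2-fold in both had the same sign. Genes of the antiviral list lay off the diagonal.

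**Figure D3:**
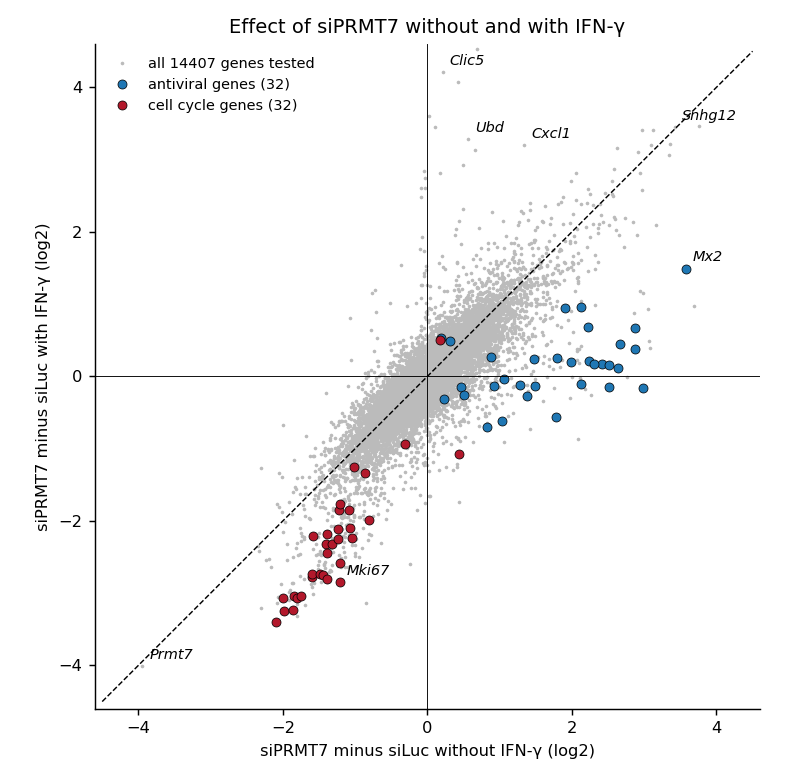
Log2 difference of siPRMT7 minus siLuc without IFN-γ (x axis) and with IFN-γ (y axis), 1 point per gene, with antiviral genes (32) in blue and cell cycle genes (32) in red. The dashed line marks equal values; the antiviral medians are 1.85 without and 0.16 with IFN-γ, and the cell cycle medians are -1.35 and -2.32.

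In siLuc cells IFN-γ raised the genes of interferon defence and class I presentation by large factors, and 31 of 32 cell cycle genes fell by smaller ones (adjusted p = 0.0654 for the list with an estimated correlation). Iigp1, an immunity-related GTPase, rose from 6.17 ± 0.07 to 16.17 ± 0.01 (log2 10.01, SE 0.18, n = 3 per group). Gbp3 rose by 7.09 (SE 0.04) and Cd274 by 3.65 (SE 0.04), from 9.70 ± 0.09 to 13.35 ± 0.04. Abca12, a lipid transporter, showed the largest fall among named genes (-2.74, SE 0.07). The comparison asks how control cells respond to the cytokine.

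All 17 interferon-inducible GTPases rose (median 7.25, camera adjusted p = 9.78e-25), as did all 32 antiviral genes (median 4.27, camera adjusted p = 3.79e-40). Both had an adjusted p = 0.0074 with an estimated correlation. Gbp4 rose by 9.60, Gbp2 by 9.37, Igtp by 9.16, Tgtp1 by 8.33, Tgtp2 by 8.27, Gbp6 by 8.002 and Gbp7 by 6.62. Oasl2 rose by 7.07, Parp14 by 6.21 and Isg15, a ubiquitin-like protein, by 4.95. Of the class I genes 19 rose and 2 fell (median 4.21, camera adjusted p = 3.1e-21; adjusted p = 0.00516 with an estimated correlation), with H2-T23 at 7.31, Nlrc5 at 7.21, H2-K1 at 5.46, Tapbp at 4.33, Psme2 at 4.08 and B2m at 3.31. Of 8 class II genes 7 rose and 1 fell (median 5.05, camera adjusted p = 3.19e-08; adjusted p = 0.0654 with an estimated correlation), with Cd74 and the transactivator Ciita at 6.17 each and H2-Ab1 at 5.19. Of the nucleic acid sensing genes 14 rose and 1 fell (median 2.0, camera adjusted p = 1.51e-12, and adjusted p = 0.00551 with an estimated correlation). Among them Zbp1 was at 8.49, Dhx58 at 4.97, Ifih1 at 3.96 and Ddx58 at 2.81. Of the signalling genes 15 rose and 3 fell (median 1.17, camera adjusted p = 1.06e-09; adjusted p = 0.0126 with an estimated correlation), with Irf1 at 5.41 and Stat2 at 4.29. Of the chemokines and cytokines 14 rose and 2 fell (median 1.16, camera adjusted p = 2.74e-08, and adjusted p = 0.024 with an estimated correlation). Among them Cxcl9 was at 6.23, Tnfsf10, which encodes TRAIL, at 5.05 and Cxcl10 at 2.81. Of the checkpoint and immune evasion genes 7 rose and 3 fell (median 0.22, camera adjusted p = 0.00629, and adjusted p = 0.061 with an estimated correlation). Among them Serpinb9 was at 3.0 and Cd47 at 2.11.

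Of 32 cell cycle genes 31 fell, 1 of them at least 2-fold (median -0.73, camera adjusted p = 5.03e-16; adjusted p = 0.0654 with an estimated correlation). Bub1 fell by 0.91, Mcm2 fell by 0.86 and Mcm3 fell by 0.85. Pigmentation genes split into 4 higher and 11 lower of 18 (median -0.24, camera adjusted p = 0.00523; adjusted p = 0.292 with an estimated correlation). The receptor kinase gene Kit fell by 1.83 and Tyr, tyrosinase, fell by 0.99. Dedifferentiation genes had 7 higher and 4 lower (median 0.40, camera adjusted p = 0.0483; adjusted p = 0.109 with an estimated correlation), with Fn1 at 1.98, Jun at 1.64 and Axl at 0.85. Of the Sm and snRNP genes 15 fell and 1 rose (median -0.28, camera adjusted p = 0.00159; adjusted p = 0.101 with an estimated correlation), including Snrpb at -0.48. Of 7 mitochondrially encoded genes 6 fell (median -0.78, camera adjusted p = 0.00245; adjusted p = 0.292 with an estimated correlation), with mt-Cytb at -1.18, beside the lower mitochondrial share given above. Of 30 ribosomal protein genes 26 fell (median -0.24, camera adjusted p = 1.92e-06; adjusted p = 0.288 with an estimated correlation).

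The remaining lists were not called, with camera adjusted p from 0.079 (p53 pathway) to 0.855 (glycolysis). Higher and lower members were 0 and 4 of 9 in the arginine methyltransferase list, which holds Wdr77, and 9 and 14 of 30 silencing genes. They were 6 and 12 of 20 p53 pathway genes, 10 and 11 of 25 stress response genes and 4 and 7 of 13 heat shock genes. They were 7 and 2 of 20 cholesterol genes, 4 and 5 of 21 glycolysis genes and 0 and 2 of 3 markers of fibroblasts and other cells. Within these lists Daxx was at 1.81, Uhrf1 at -0.82, Dnmt3a at -0.68, Ezh2 at -0.65, Dnmt1 at -0.62 and Dnmt3b at -0.55. Atf3 was at 2.26 and Nupr1 at 1.21, Zmat3 at -1.004 and Perp at -1.13, Hsd17b7 at 1.15, Wdr77 at -0.40, Prmt1 at -0.28 and Col1a2 at -1.61. The median of -0.00 and mean of 0.10 of the stress response list differed in sign, and the median of the cholesterol list, 0.04, turned to -0.01 under median centring. Other large falls were Car6 at -2.08, Etv5 at -1.96, Zfp469 at -1.92, Adam19 at -1.89, Pomk at -1.83 and Fam81a at -1.83, and Apol6 rose by 8.28. Adjusted over the list alone, 15 nucleic acid sensing genes and 15 chemokines and cytokines rose. With that adjustment 12 pigmentation, 8 heat shock and 28 ribosomal protein genes fell, and the glycolysis list went to 3 higher and 4 lower. In all, 8737 genes were called, 4029 higher and 4708 lower, and under quantile normalization the split was 3133 higher and 6063 lower. At least 2-fold changes were 658 rises and 145 falls, and against a 2-fold null 505 and 54. The authors' deposited table calls 6886 of the genes tested, 6863 of them also called here in the same direction. The libraries of the groups did not overlap for 62.1% of genes, where chance gives 10%.

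In siPRMT7 cells IFN-γ raised the same kinds of genes and lowered cell cycle genes at least 2-fold. Iigp1 rose by 8.98 (SE 0.18, n = 3 per group), from 7.12 ± 0.70 to 16.10 ± 0.04, and Gbp3 by 4.32 (SE 0.04), from 9.60 ± 0.06 to 13.92 ± 0.03. The shared SE of Iigp1 understates the spread of its untreated siPRMT7 libraries. Mki67, the gene of the proliferation marker Ki-67, fell by 2.72 (SE 0.05), from 13.03 ± 0.05 to 10.31 ± 0.08. Cd274 rose by 3.70 (SE 0.04), from 10.20 ± 0.06 to 13.91 ± 0.04. The comparison asks how cells with little Prmt7 RNA respond to the cytokine.

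Of 32 cell cycle genes 31 fell, all of these at least 2-fold, and 1 rose (median -1.80, camera adjusted p = 5.31e-28; adjusted p = 0.0206 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, fell by 2.21 and Ccnd1, cyclin D1, fell by 1.99. Pclaf, Pbk, E2f8 and Tk1, which are also linked to proliferation, were at -2.53, -2.48, -2.42 and -2.29. Of the antiviral genes 31 rose and 1 fell (median 2.701, camera adjusted p = 1.35e-32), and all 17 GTPases rose (median 5.94, camera adjusted p = 1.43e-24). Both had an adjusted p = 0.0102 with an estimated correlation. Gbp4 rose by 9.07, Tgtp1 by 8.14, Gbp10 by 7.80, Igtp by 6.64 and Gbp6 by 5.86. Oasl2 rose by 4.93, Parp14 by 4.20 and Ifit2 by 3.84. Gbp10 shares exons with an overlapping predicted gene, so its value is uncertain. Of the class I genes 19 rose and 3 fell (median 3.26, camera adjusted p = 3.19e-20; adjusted p = 0.00626 with an estimated correlation), with Nlrc5 at 5.95, H2-T23 at 5.37, Tapbpl at 4.41, H2-K1 at 3.75, Psme2 at 3.29 and B2m at 2.60. Of the class II genes 7 rose and 1 fell (median 5.83, camera adjusted p = 3.67e-09; adjusted p = 0.0495 with an estimated correlation), with Cd74 at 7.03, H2-Aa at 7.02 and H2-Ab1 at 6.41. Of the chemokines and cytokines 17 rose and 1 fell (median 1.82, camera adjusted p = 1.83e-11), with Cxcl9 at 7.26, Cxcl10 at 2.99 and Csf1 at 1.91. Of the nucleic acid sensing genes 14 rose and 2 fell (median 0.94, camera adjusted p = 3.84e-09). Among these Zbp1 was at 7.59, Dhx58 at 4.10, Samhd1 at 2.81, Ifih1 at 2.32 and Ddx58 at 1.09. The chemokine and cytokine list and the sensing list each had an adjusted p = 0.0102 with an estimated correlation. Of the signalling genes 15 rose and 2 fell (median 0.82, camera adjusted p = 3.08e-09; adjusted p = 0.0123 with an estimated correlation), with Irf1 at 4.81 and Stat2 at 3.66.

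The checkpoint list had 7 higher and 4 lower (median 0.17, camera adjusted p = 0.0178; adjusted p = 0.0781 with an estimated correlation), with Serpinb9 at 2.7 and Cd47 at 1.83. Pigmentation genes had 5 higher and 13 lower (median -0.37, camera adjusted p = 0.000921; adjusted p = 0.294 with an estimated correlation), with Kit at -2.25, Tyr at -1.34 and Slc45a2 at -1.05. The dedifferentiation list had 8 higher and 2 lower (median 0.48, camera adjusted p = 0.0178; adjusted p = 0.076 with an estimated correlation), with Fn1 at 1.42 and Axl at 1.17. Of the cholesterol genes 16 fell (median -0.27, camera adjusted p = 0.000563; adjusted p = 0.377 with an estimated correlation), and of the Sm genes 14 fell and 3 rose (median -0.17, camera adjusted p = 0.0142; adjusted p = 0.206 with an estimated correlation). Of the mitochondrially encoded genes 6 fell (median -0.69, camera adjusted p = 0.000921; adjusted p = 0.317 with an estimated correlation), and of the ribosomal protein genes 23 fell and 1 rose (median -0.19, camera adjusted p = 5.44e-05; adjusted p = 0.355 with an estimated correlation). The other lists were not called, with camera adjusted p from 0.0608 (p53 pathway) to 0.931 (stress response, whose median of -0.14 and mean of 0.12 differed in sign). Higher and lower members were 1 and 3 of the methyltransferase list, 9 and 13 of the silencing genes and 4 and 12 of the p53 pathway genes. They were 11 and 13 of the stress response genes and 5 and 3 of the heat shock genes. The glycolysis genes had 10 and 2, and the fibroblast and other markers 0 and 1. The heat shock median of 0.05 turned to -0.02 under quantile normalization. Within these lists Uhrf1 fell by 2.14, Hells fell by 1.25, Dnmt1 fell by 1.18, Dnmt3a fell by 0.49 and Dnmt3b fell by 0.35, while Fas rose by 1.69, Daxx by 1.55, Atf3 by 1.47 and Hspb1 by 1.33. Other named genes were BC023105 at 8.16, Etv5 at -2.71 and Cntn1 at -2.31. Adjusted over the list alone, 5 checkpoint and immune evasion genes, 7 mitochondrially encoded and 25 ribosomal protein genes fell. In all, 8156 genes were called, 4037 higher and 4119 lower, and under quantile normalization 3473 higher and 5011 lower. At least 2-fold changes were 515 rises and 388 falls, and against a 2-fold null 420 and 253. The authors' deposited table calls 7150 of the genes tested, 7049 of them also called here in the same direction. The libraries of the groups did not overlap for 65.3% of genes, where chance gives 10%.

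**Figure D4:**
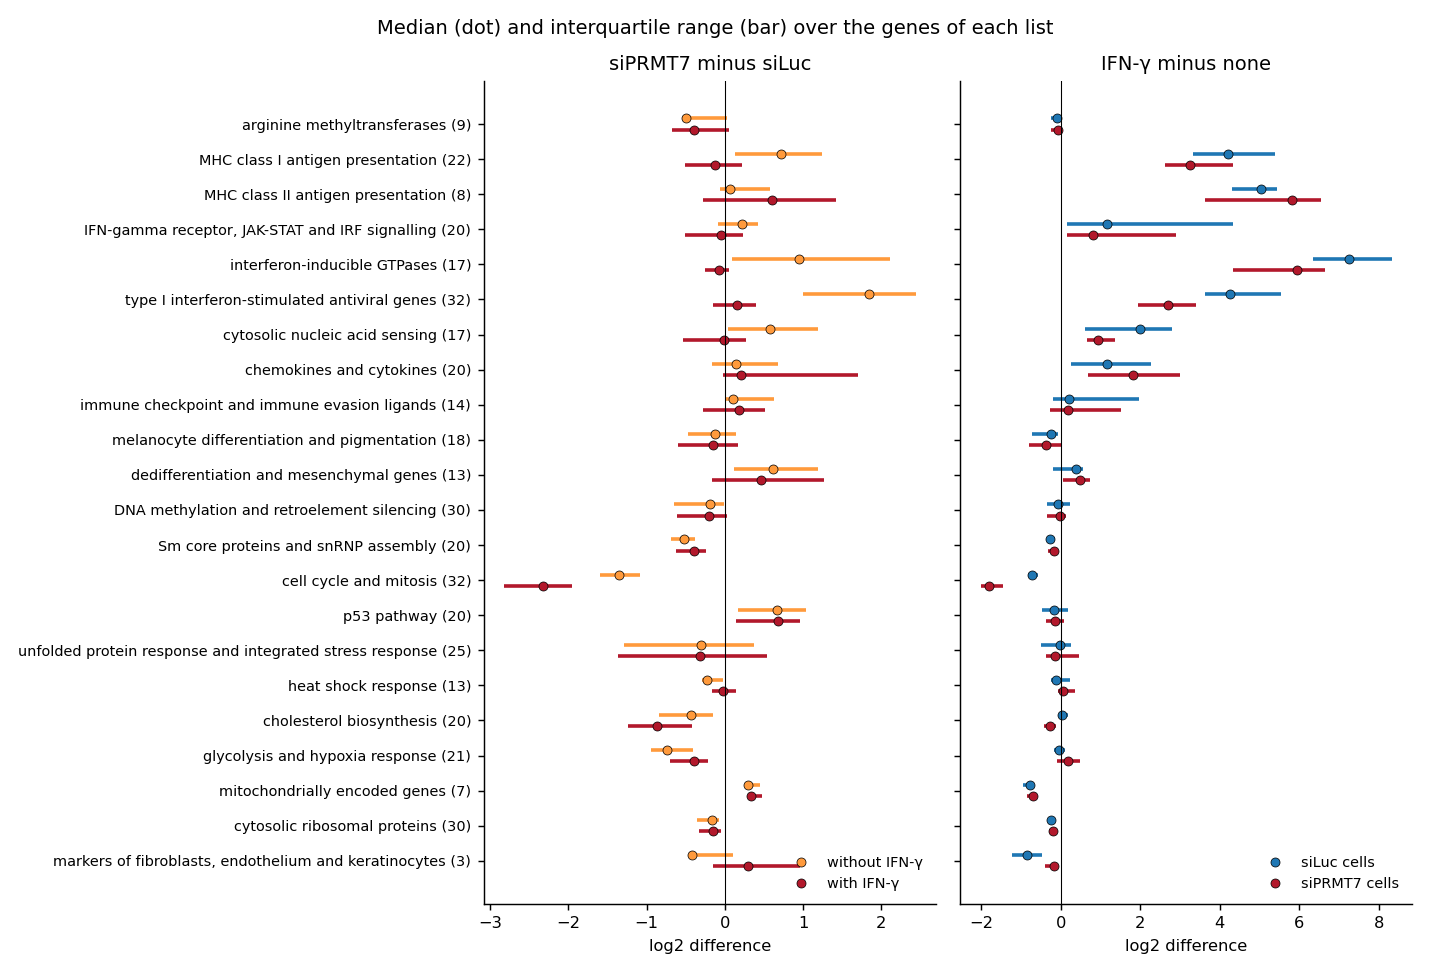
Median (dot) and interquartile range (bar) of log2 differences (x axes) over the measured members of each list (y axis, number measured in brackets), for siPRMT7 minus siLuc (left) and IFN-γ minus none (right). The antiviral median is 1.85 without and 0.16 with IFN-γ on the left, and 4.27 in siLuc and 2.701 in siPRMT7 cells on the right.

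The IFN-γ response itself differed between siPRMT7 and siLuc cells, by a test of the difference of the responses. It was smaller in siPRMT7 cells for 30 of 32 antiviral genes, and also for Gbp3 (difference of responses -2.77, SE 0.05, adjusted p = 4.4e-19, n = 3 per group) and Isg15 (-2.22, SE 0.06). It was larger for Clic5 (3.997, SE 0.12, adjusted p = 5.56e-16), Ubd (2.72, SE 0.12) and the class II gene H2-Aa (2.01, SE 0.11). The H2-Aa value is uncertain: the authors' deposited table gives a response of 10.11 in siPRMT7 cells, well above the rlog value, so shrinkage affects it. For cell cycle genes the fall was larger in siPRMT7 cells. For Cd274 no difference passed the threshold (0.05, SE 0.06, adjusted p = 0.594).

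Of 32 antiviral genes 30 had a smaller response in siPRMT7 cells, 25 by at least 2-fold, and 1 a larger one (median -1.64, camera adjusted p = 6.49e-41; adjusted p = 0.007 with an estimated correlation). Usp18, an ISG15 protease, was at -3.14, Trim30a, outside the list, at -2.58, Xaf1 at -2.48 and Parp14 at -2.02. Of 17 GTPases 11 had a smaller response and 1 a larger one (median -1.31, camera adjusted p = 6.62e-11; adjusted p = 0.0549 with an estimated correlation), with Irgm1 at -2.35 and Gbp7 at -2.28. Of the class I genes the difference was negative for 17 and positive for 1 (median -0.91, camera adjusted p = 1.7e-15). For the nucleic acid sensing genes, 12 were negative and 0 positive (median -0.77, camera adjusted p = 4.68e-11). Both had an adjusted p = 0.007 with an estimated correlation. H2-K1 was at -1.71, Nlrc5 at -1.264, B2m at -0.71, Ddx58 at -1.72 and Ifih1 at -1.65. Of the signalling genes 12 were negative and 1 positive (median -0.28, camera adjusted p = 1.12e-05, and adjusted p = 0.0549 with an estimated correlation), with Irf1 at -0.59. Of the class II genes 5 were positive and 3 negative (median 0.67, camera adjusted p = 0.041, and adjusted p = 0.494 with an estimated correlation). In the authors' deposited table the responses were not larger in siPRMT7 cells for H2-Ab1 (10.41 in siLuc, 8.70 in siPRMT7) or Cd74 (7.43 and 7.34). The positive median may thus come from shrinkage of low values, which was not tested for this list. Of the chemokines and cytokines 11 were positive and 2 negative (median 0.29, camera adjusted p = 0.00727, and adjusted p = 0.257 with an estimated correlation). The deposited table gives responses of 9.42 in siLuc and 9.24 in siPRMT7 cells for Cxcl9, and 2.87 and 3.03 for Cxcl10. Cxcl10 was at 0.18 (adjusted p = 0.0322), a call lost under 8 alternatives, among them variances without the trend (adjusted p = 0.0658).

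In the cell cycle list the difference was negative for 31 of 32 genes, 21 of them at least 2-fold, and positive for 1 (median -1.11, camera adjusted p = 1.98e-35; adjusted p = 0.0186 with an estimated correlation). It was negative for 16 of 20 cholesterol genes (median -0.35, camera adjusted p = 3.01e-07; adjusted p = 0.328 with an estimated correlation). It was positive for 5 of 13 heat shock genes (median 0.11, camera adjusted p = 0.0082; adjusted p = 0.328 with an estimated correlation) and for 2 of 21 glycolysis genes (median 0.13, camera adjusted p = 0.0378; adjusted p = 0.737 with an estimated correlation). The other lists were not called, with camera adjusted p from 0.081 (fibroblast and other markers) to 0.839 (mitochondrially encoded genes). Positive and negative members were 2 and 6 of 14 checkpoint and immune evasion genes, 3 and 7 of 18 pigmentation genes and 5 and 5 of 13 dedifferentiation genes. They were 6 and 9 of 30 silencing genes, 7 and 4 of 20 p53 pathway genes and 8 and 5 of 25 stress response genes. The Sm genes had 1 and 0 of 20 and the ribosomal protein genes 3 and 1 of 30. Dnmt1 was at -0.56 (adjusted p = 3.12e-07), Dnmt3a at 0.19 (adjusted p = 0.0263) and Dnmt3b at 0.20 (adjusted p = 0.215). The Dnmt3a call was lost under 9 alternatives, among them no filter (adjusted p = 0.0768) and variances without the trend (adjusted p = 0.0597). Adjusted over the list alone, 18 class I and 18 cholesterol genes were negative, and 2 antiviral, 7 silencing and 2 ribosomal protein genes positive.

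Other genes with the smallest p for a positive difference were Clvs1 at 1.61, the linker histone gene H1f0 at 1.29, Asph at 1.23, Sun2 at 0.92 and Fzd7 at 0.91. Clvs1 shares 30.4% of its exon bases with Asph on the opposite strand, and the use of strand in the counting is not given in the sources used here, so its value is uncertain. In all, 4415 genes were called for the difference, 2034 positive and 2381 negative, and under median centring 2852 positive and 1993 negative. At least 2-fold differences were 63 positive and 279 negative, and against a 2-fold null 28 and 115.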

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

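Of the tests in this part, those of carry-over of treated material, of the shrinkage of low values and of a like end level were chosen after the results were seen. What brought the results here is that the IFN-γ response differed between siPRMT7 and siLuc cells, by the interaction test. It did so for 4415 genes. The values are the response in siPRMT7 cells minus that in siLuc cells, on the log2 scale.

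Larger or more positive in siPRMT7 cells were Clic5 at 3.997, Ubd at 2.72, H2-Aa at 2.01, Zfp469 at 1.91, Cxcl1 at 1.86, BC023105 at 1.82, Clvs1 at 1.61 (uncertain for its overlap with Asph), Abca12 at 1.55, H1f0 at 1.29, Asph at 1.23, Sun2 at 0.92, Fzd7 at 0.91, Dnmt3a at 0.19 and Cxcl10 at 0.18. For Abca12 and Dnmt3a this was a smaller fall, and the calls of Dnmt3a and Cxcl10 were lost under 9 and 8 alternatives. The larger response of H2-Aa, and that of the class II list below, may come from shrinkage of low values, which was not tested for them. Zfp469 fell in siLuc cells without a called change in siPRMT7 cells (-0.0098, adjusted p = 0.932). Among interferon genes the difference was negative for Usp18 at -3.14, Gbp2 at -2.95, Gbp3 at -2.77, Trim12c at -2.71, Irgm2 at -2.70, Trim30a at -2.58, Igtp at -2.52, Xaf1 at -2.48, Irgm1 at -2.35, Gbp7 at -2.28, Isg15 at -2.22, Oasl2 at -2.14, Gbp6 at -2.14, Mx2 at -2.08, Parp14 at -2.02 and Tgtp2 at -2.01. It was also negative for H2-T23 at -1.95, Ddx58 at -1.72, H2-K1 at -1.71, Ifih1 at -1.65, Tapbp at -1.63, Samd9l at -1.54, Oas1a at -1.52, H2-D1 at -1.44, Eif2ak2 at -1.41, Nlrc5 at -1.26, B2m at -0.71 and Irf1 at -0.59. Genes of division and DNA methylation with a negative difference were Mki67 at -1.64, E2f8 at -1.55, Espl1 at -1.52, Ccnd1 at -1.52, Kntc1 at -1.46, Pclaf at -1.46, Rrm2 at -1.38, Birc5 at -1.38, Pbk at -1.37, Uhrf1 at -1.32, Mcm5 at -1.31, Bub1 at -1.25 and Dnmt1 at -0.56. Called lists, by their medians, were the antiviral genes at -1.64, GTPases at -1.31, cell cycle at -1.11, class I presentation at -0.91, nucleic acid sensing at -0.77, cholesterol synthesis at -0.35, signalling at -0.28, heat shock at 0.11, glycolysis at 0.13, chemokines at 0.29 and class II presentation at 0.67. With an estimated correlation the calls were lost for GTPases and signalling (adjusted p = 0.0549 each), chemokines (adjusted p = 0.257), cholesterol and heat shock (adjusted p = 0.328 each), class II (adjusted p = 0.494) and glycolysis (adjusted p = 0.737).

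The antiviral genes were higher in siPRMT7 cells without IFN-γ, and carry-over of treated material would raise them too. The 31 called genes needed a median share of 11.5% of treated material, 10.4 times the highest ratio of untreated to treated level among the 20 most induced genes (1.10%), and 30 of them needed more than that ratio. The higher values of the replicate 3 library, a median of 0.179% of the treated level over the lowest library of its group, are therefore too small for the rise, and carry-over was argued against. So was scaling between libraries, since the lowest median of the list under another scaling was 1.81. An effect of the siPRMT7 reagent other than loss of PRMT7 cannot be told apart, since the labels name 1 reagent.

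The cell cycle genes were lower in siPRMT7 cells with IFN-γ. Scaling was argued against, with a median of -2.24 under the scaling that brought it nearest to 0. Of 10000 random lists matched on mean level, 0% had a median as low (lowest -0.42), so genes of like level did not fall alike. The values are already scaled for library size, which keeps such medians near 0, so this cannot decide on lower depth of these libraries. A slower cycle or fewer dividing cells stay open as biological readings, and other effects of the reagent were not tested for this pattern.

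The IFN-γ response of antiviral genes was smaller in siPRMT7 cells. Shrinkage of low values by the rlog transformation was argued against, since the authors' deposited table gives a median of -2.06. With IFN-γ the antiviral genes differed between siPRMT7 and siLuc cells by a median of 0.16 (quartiles -0.15 and 0.40), 16 of 32 higher and 12 lower. This median and the starting difference together make up the difference of the responses, so a higher starting level with a like end level and a weaker response cannot be told apart.

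For each comparison of a pair of groups, the 10 splits of 6 libraries are too few for a share under 0.05. The real split (1 of 10 in every comparison) alone reached its count, and the highest count of another split was 0. The other splits mix the groups, which puts the group difference into the spread and keeps such counts low. For the interaction, 3 of 100 assignments of the 12 libraries, the real one included, gave as many called genes. These assignments also mix siRNAs and treatments within groups. The effects of both widen the spread, so the share cannot decide on chance for the interaction. The highest other count was 5520, and its sides held 5 and 1 libraries with IFN-γ; the next, with 4702, held 0 and 6. Another assignment with the same numbers of libraries per side as the first gave 0 called genes. The make-up of the 4 groups within each was not compared, so the cause of the count of 5520 was not tested.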

How the results depend on the processing

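Counts of called genes kept within 1.5 times under all alternatives but a minimum log2 difference of 1, which by its stricter threshold left 1179 genes (siPRMT7 without IFN-γ), 1273 (siPRMT7 with IFN-γ), 803 (IFN-γ in siLuc cells), 903 (IFN-γ in siPRMT7 cells) and 342 (interaction). The Prmt7 difference ran from -4.07 to -3.88 over all alternatives. In the same order of comparisons camera called 13, 6, 14, 15 and 11 lists, and with an estimated correlation 0, 0, 6, 8 and 4, so the list calls of both siPRMT7 against siLuc comparisons rest on the preset correlation. Directional fry called 20 and 21 lists in the siPRMT7 comparisons, and mixed fry 22, 22 and 22 in the first 3 comparisons and 19 in the interaction. The correlation of the siPRMT7 effects was 0.822 with no filter, 0.844 at a mean rlog value of at least 6 and 0.828 to 0.833 with a library left out. Of 5787 alternatives for named genes 5743 kept their side and direction, 23 were weaker, 7 stronger and 14 reversed, and the cause was not tested. Reversed were values near 0 in the main fit. Cxcl10 (siPRMT7 with IFN-γ) was at 0.27 under quantile normalization, where it was called (adjusted p = 8.53e-06). It was at 0.084 under median centring, 0.012 with library weights and -0.022 to 0.039 with a library left out. B2m (same comparison) was at 0.29 under quantile normalization, also called there (adjusted p = 0.000197), and 0.048 under median centring. Prmt7 (IFN-γ in siLuc cells) was at -0.030 under quantile normalization, -0.044 under median centring, -0.032 with weights and -0.034 to 0.055 with a library left out. Prmt7 (IFN-γ in siPRMT7 cells) was at -0.11 to 0.035 with a library left out. Cd274 (interaction) was at -0.0066 with weights. The replicate numbers were not taken as pairs, since not every correlation of deviations between libraries of the same number was over 0.1 (5 of 18; -0.12 to 0.22, median 0.063, against 3 of 36 and a median of -0.021 for different numbers). The labels name the numbers as series 1 to 3 in all 4 groups and do not say what a series shared, and 8 of 12 libraries correlated best with their own number, so a shared origin stays open. With the number as a block 10896, 10837, 8855, 8273 and 4573 genes were called; ribosomal protein genes with IFN-γ passed (adjusted p = 0.0495), dedifferentiation genes in siLuc cells did not (adjusted p = 0.0506), and no other list call changed. Depth and shrinkage limit what is seen of weakly expressed genes.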

Other observations

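The genes and lists of this part were chosen after values were seen, and the test of an IFN-γ-like state was chosen after its result was seen.

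Several genes outside the lists were highest in siPRMT7 cells with IFN-γ. Nos2, the inducible nitric oxide synthase, had group means of 3.76 in siLuc cells, 5.71 in siLuc cells with IFN-γ, 3.68 in siPRMT7 cells and 8.20 in siPRMT7 cells with IFN-γ (difference of responses 2.57). Acod1, which makes itaconate, had a difference of responses of 2.64 and Krt16, a stress keratin, of 2.63. Kcnt2 was at 3.64, Adgrv1 at 3.58, Nrxn3 at 3.35, Dmrtc1a at 2.89, Col6a3 at 2.77, Klf4 at 1.92 and Tnfaip3 at 1.57. Against a null of a 2-fold change, 28 genes were positive in this test.

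The stress response list, not called as a list, had 8 members higher and 14 lower in siPRMT7 cells without IFN-γ, and no part of it was tested. Among chaperones of the endoplasmic reticulum, Hspa5 fell by 1.29, Hsp90b1 fell by 1.38, Creld2 fell by 1.45, Pdia4 fell by 1.33 and Hyou1 fell by 1.257. Xbp1, a regulator of these genes, fell by 1.07. Phgdh and Psat1, of serine synthesis, fell by 1.88 and fell by 0.30. The 8 higher members were Atf3 at 2.08, Nupr1 at 1.17, Ddit3 and Sesn2 at 1.14 each, Ppp1r15a at 1.005, Trib3 at 0.59, Atf4 at 0.38 and Dnajb9 at 0.20, while Asns, Chac1 and Cebpb were not called.

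The rise of Ubd, Cxcl1, Tnfaip3 and Nfkbie led to a test of a wider NF-κB response in siPRMT7 cells with IFN-γ. Of 19 other NF-κB targets the difference of the responses was positive for 15 and negative for 0 (median 0.48, camera p = 3.95e-09, and p = 0.00165 with an estimated correlation). For Traf2 and Nfkb2 the response changed sign, from -0.27 and -0.23 in siLuc cells to 0.21 and 0.40 in siPRMT7 cells. Cxcl2 was at 2.43, Tnf at 1.17, Nfkbia at 0.93 and Relb at 0.92. In siPRMT7 cells all 19 rose with IFN-γ, and in siLuc cells 10 rose and 2 fell. Of these 19 genes, 4 (Ccl2, Tnf, Cxcl2 and Csf1) also stand in the chemokine and cytokine list. The values are consistent with a wider NF-κB response, and NF-κB itself was not measured.

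Snhg12 led to a test of other small nucleolar RNA host genes, whose spliced RNAs are often targets of nonsense-mediated decay. Of 12 measured, 9 were higher in siPRMT7 cells without IFN-γ and 1 lower (median 0.84, camera p = 0.000349; p = 0.13 with an estimated correlation). Snhg6 was at 1.66, Zfas1 at 1.58, Gas5 at 1.35, Snhg15 at 1.31 and Snhg3 at -0.47. Lower decay may raise them, and slower translation or growth arrest may as well, which was not tested. IFN-γ, which lowered the cell cycle list too, did not raise the host genes (0 higher and 8 lower in siPRMT7 cells, 1 higher and 6 lower in siLuc cells). In siLuc cells that fall of the cell cycle list was not called with an estimated correlation. A like test of neuronal genes that REST represses, prompted by Stmn4, Cacna1a, Sv2b and Epha7, did not pass (3 of 9 higher, 1 lower, camera p = 0.398; p = 0.481 with an estimated correlation), so no wider rise was seen.

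The genes raised by siPRMT7 without IFN-γ overlapped those raised by IFN-γ in siLuc cells. Of 670 genes raised at least 2-fold by siPRMT7, 161 (24.0%) were among the 658 raised by IFN-γ, 5.26 times the 30.6 expected of independent lists, and 42 were lowered by both where 5.12 were expected. The 3 untreated siLuc libraries serve as controls of both, and sharing them alone gave a simulated r of 0.498 across genes (observed 0.349) and a simulated covariance of 0.00343 (observed 0.155). Some IFN-γ-induced genes rose little or not at all: Irf1 rose by 0.23 for siPRMT7 (5.41 for IFN-γ), Cxcl10 was at -0.18 (2.81), and H2-Aa was at -0.077 (5.01, not called for siPRMT7), though 3 of the 8 class II genes rose, Cd74 by 1.08. For H2-Aa, shrinkage of low values may hide a rise without IFN-γ. By Irf1 and Cxcl10, the overlap thus covers part of the IFN-γ response only. No cells were given type I interferon, so an IFN-γ-like and a type I interferon-like state cannot be told apart.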
